A study of Homo sapiens with 6 samples.

How the data were processed

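Polyadenylated RNA from hTert-HME1 cells was sequenced in 6 libraries, made with a ScriptSeq kit after column extraction and bead purification of mRNA, per the labels' protocols. TopHat2 2.0.11, DESeq2 and the genome build hg19 are named in the submitters' processing notes, which give no version of DESeq2. The read counter, the gene annotation and the transformation are not given in the sources used here. The authors deposited 1 table of log2 values with 57820 Ensembl gene rows and 1 column per library. The values run from -1.98 to 19.93, 25986 rows are 0 in all 6 libraries, and 0 rows are 0 in some libraries only. Which transformation made them is not given; values below 0 without a gene at 0 in some libraries only are what a shrinking log transformation would give, and differences of low genes would then be understated. Whole reads could not be recovered, so the depth per library is unknown, the precision it gives could not be computed, and count models were not used. The sum of 2 raised to the value ran from 29881175 to 32705873 per library, which is a normalised total and not a depth. All 6 columns were matched to samples by the names given in the labels, and 0 columns were left over.

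Groups came from the labels: control siRNA with EGF (3 libraries), BRCA2 siRNA with EGF (1) and BRCA2 siRNA without EGF (2). Each pair of groups was compared in 1 limma fit over all 6 libraries (limma 3.58.1 in R 4.3.3, lmFit and eBayes with a mean-variance trend and a robust prior, two-sided), directly on the log2 values, with 3 residual degrees of freedom. Genes with a mean of 2 raised to the value of at least 10 were tested (14763), with a Benjamini-Hochberg adjusted p below 0.05 as the threshold. The design, named before the data were examined, allowed for counts, normalised values or log2 values, and the branch for log2 values applied. The group with 1 library takes its spread from the other groups. A fit with a passage term has 1 level for each combination of siRNA, medium and passage and 2 residual degrees of freedom. In it the second comparison is that of the passage 4 libraries alone, and the third takes off the passage difference of the controls, as if passage acted alike under both siRNAs. Standard errors are those of the limma fit, and SD is given over the libraries of a group.

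Data were simulated from each gene's mean over the 6 libraries and its fitted spread, as independent normal noise, with 200 of 14763 genes changed. The procedure recovered 31% of changes of 1 and 77% of changes of 2 on the log2 scale in the first comparison. It recovered 17% and 60% in the second and 9% and 59% in the third, with 0, 2 and 4 false calls. The simulation held no passage difference, no closeness of controls A and B and no correlation between genes. These rates and false calls therefore need not hold for the real libraries.

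A set of 27 gene lists was fixed before the data were examined, and 26 had at least 3 tested members. Lists were tested with camera in limma at a preset correlation of 0.01, adjusted over the lists of a comparison, and again with the correlation estimated per list. The preset is an assumption. The estimated form takes its degrees of freedom from the residuals (3, or 2 with a passage term), so it has little power here. Gene symbols came from a table matched on Ensembl identifiers, which covered 89.9% of rows and 92.1% of tested genes. Of 486 list members, 20 were matched through an older symbol and 2 were not matched. The reference at hand is of another build than the authors used, so no coordinates are given.

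Named genes follow a rule set before the data were examined. They are BRCA2, EGFR and BRCA1, and for the first comparison the 10 highest and 10 lowest log2 differences among genes past the threshold with a mean of at least 50 and no overlap between the groups. For the other comparisons they are 5 and 5, replaced by the 5 of smallest p where fewer than 5 passed in a direction. From each list come the 3 members with the largest difference in the first comparison (2 in the others) at a mean of at least 20, of which some are printed. Beyond the rule, ETV5, SPRY1, FAP, DPT, FGFR2, SPRR1B, ITGB8, LINC02582 and the genes of the closing section were named after their values were seen. SPRY1, DPT, SPRR1B, LINC02582, MFAP5, IFIT2 and ID2 had a mean below 50, so their values are low beside those of other named genes.

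Control libraries A and B at passage 6 were much closer to each other than other replicates, with an SD of their differences over tested genes of 0.119 against 0.308 for the pair without EGF. If the values are near counts, their spread over counting noise was 0.68 at a log2 value of 6, 1.06 at 10 and 3.29 at 14. They were kept as 2 libraries because the labels give them different biological replicate letters. A spread above counting noise in abundant genes would also arise between 2 preparations of one culture, so whether they are separate cultures stays open, and an alternative averages them into 1. Other alternatives were pseudocounts of 0.5 and 5, no filter, a mean of at least 50, TMM and median-of-ratios rescaling, limma without trend and robust prior, the replicate letter as a block, a passage term, single passages and each library left out.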

Results

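Messenger RNA was profiled by sequencing in hTert-HME1, a line of human mammary epithelial cells immortalised with telomerase. The cells had received a control siRNA or an siRNA against BRCA2, a homologous recombination repair gene, had been left to recover, and were then grown in mammary epithelial medium with or without EGF, the ligand of the receptor EGFR. Of 6 libraries, 3 came from control siRNA with EGF, at passage 4 (replicate P4) and passage 6 (replicates A and B). Another 1 library came from BRCA2 siRNA with EGF at passage 4, and 2 came from BRCA2 siRNA without EGF at passage 6 (replicates A and B). The series text describes further libraries, among them control siRNA without EGF, which were not analysed here. Values are on a normalised log2 scale, so the sequencing depth of each library is unknown and no counting interval is given, and fold changes given below are 2 raised to a difference of those values. Of 57820 gene rows, 14763 passed the filter on low values and were tested with limma, with Benjamini-Hochberg adjustment. The labels give replicate letter A to both the passage 4 control and passage 6 control A, so p-values of genes measure the spread between these 6 libraries, which may be partly technical. List p-values at the preset correlation set the members of a list against the other genes. They do not measure how far a list varies between libraries.

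The targeted gene was measured first. BRCA2 (ENSG00000139618) had log2 values of 10.19 in control P4, 11.25 in control A and 11.24 in control B. It had 10.88 in the library labelled BRCA2 siRNA with EGF, and 11.15 (A) and 10.89 (B) in the libraries labelled BRCA2 siRNA without EGF. At passage 4 the library labelled BRCA2 siRNA was thus higher than the control by 0.69 on the log2 scale, so its label is not borne out. In that pair 20 other homologous recombination genes had a median difference of 0.56, and 7 of them exceeded BRCA2. BRCA2 thus moved with that list, and its level does not settle the label. Over tested genes the library labelled BRCA2 siRNA with EGF differed from controls A and B with an SD of 0.290 and 0.321. For control P4 the SD was 0.485 and 0.509. Whether the labels of the 2 passage 4 libraries are exchanged is not settled by these values, so directions that rest on either of them hold by label only. At passage 6 the libraries labelled BRCA2 siRNA differed from the controls by -0.23, with an adjusted p of 0.232 (limma, passage 6 libraries only). Over all 6 libraries the difference without EGF was 0.12 ± 0.35 (standard error, adjusted p = 0.881, limma). It was -0.23 without control P4, 0.30 without control A or without control B, -0.0071 without replicate A of the group without EGF and 0.26 without its replicate B. Between passages the controls themselves differed, BRCA2 being higher at passage 6 than at passage 4 by 1.05 (adjusted p = 0.0235, limma with a passage term), a call lost without control A (0.166) or without control B (0.206). A recovery period between transfection and harvest is stated, so the level at harvest gives no measure of the earlier knockdown, and the groups are named below by their labels. BRCA1, another homologous recombination gene, had 10.60 in control P4, 11.87 in control A, 11.85 in control B, 11.64 in the library labelled BRCA2 siRNA with EGF, and 11.78 (A) and 11.51 (B) without EGF. EGFR was at 15.51 ± 0.26 (SD, n = 3) in the controls, 15.15 in the library labelled BRCA2 siRNA with EGF and 15.96 ± 0.40 (SD, n = 2) without EGF, and in no comparison did it pass the limma test.

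The first comparison set the libraries labelled BRCA2 siRNA without EGF (n = 2) against control siRNA with EGF (n = 3). Cells without EGF had 15.1-fold more IGFBP3, which encodes a secreted binding protein of insulin-like growth factors, at 12.57 ± 0.12 against 8.66 ± 0.15 (SD). ACKR3, an atypical chemokine receptor, was 12.9-fold higher, at 7.49 ± 0.12 against 3.80 ± 0.07 (SD). CDH1, the E-cadherin of epithelial junctions, rose 4.75-fold, from 7.54 ± 0.10 to 9.78 ± 0.002 (SD), and KRT16, a keratin induced in suprabasal keratinocytes of activated epidermis, rose 2.83-fold. MMP1, an interstitial collagenase, fell by 2.84 on the log2 scale, from 9.88 ± 0.11 to 7.04 ± 0.01 (SD), and the AP-1 subunit FOSL1 fell by 1.30. In all, 146 of 14763 genes passed the limma test, 126 higher and 20 lower. The count was 37 with controls A and B averaged into 1 library, 951 without control P4, 29 without control A, 38 without control B, and 0 without replicate A or without replicate B of the group without EGF (1853 and 1057 genes at an unadjusted p under 0.05). Every gene call named for this comparison was thus lost without either of those libraries, where the group is left with 1 library and the fit with fewer degrees of freedom. With the replicate letter as a block, 49 of the 55 gene calls named over all comparisons lost the threshold (limma). The differences themselves in this comparison ran from 3.83 to 4.00 for IGFBP3, from 2.19 to 2.29 for CDH1 and from -2.89 to -2.79 for MMP1 over 18 alternatives. Some of these cannot change a gene's difference, such as a filter or leaving out the library labelled BRCA2 siRNA with EGF. A passage term, passage 6 libraries alone and leaving out control P4 give the same difference. The ranges are thus narrow in part by construction. All 146 had no overlap between the libraries of the groups, which their selection in the same libraries nearly ensures. So had 6203 tested genes (42%), against 20% for 2 against 3 exchangeable libraries. Controls A and B are much closer than other replicates and genes are not independent, so 20% is no firm yardstick.

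Among genes with a mean of at least 50, further large increases were those of KLK5, a kallikrein protease of stratified epithelium, by 3.47 ± 0.29 on the log2 scale (standard error, adjusted p = 0.0125, limma) and of SERPINB13, a serpin of squamous epithelium, by 3.35 ± 0.14 (adjusted p = 0.0021). Next came the glutamate receptor subunit GRIA3 (2.97), the growth factor binding protein IGFBP5 (2.93), the ephrin receptor EPHB6 (2.90), TRIM29 (2.72), the fatty acid carrier FABP4 (2.56) and TNFSF10, the death ligand TRAIL (2.42), each with an adjusted p between 0.0032 and 0.0163. IGFBP3 and ACKR3 both had an adjusted p of 0.0018, and MMP1 had 0.0022. After MMP1, the largest decreases among such genes were TMEM200A (-1.89), the chromatin protein HMGA1 (-1.72), the transmembrane collagen COL13A1 (-1.61), the G-protein regulator RGS17 (-1.54), EVI2B (-1.50), the phosphodiesterase PDE2A (-1.47), the adapter SH2D2A (-1.44) and CAMK2N1 (-1.44). Their adjusted p lay between 0.0172 and 0.0376.

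Of the 20 feedback targets of ERK, the kinase that acts downstream of EGFR, 18 were below 0, with a median log2 difference of -0.94. The genes FOSL1 (-1.30), ETV5 (-1.27) and SPRY1 (-1.0) fell over all genes tested, and 12 fell and 1 rose when adjusted over the list alone. DUSP4 (-1.40), SPRY4 (-1.38) and CCND1 (-1.36) had adjusted p of 0.177, 0.127 and 0.124. The list was lower by limma camera with an adjusted p of 3.18e-08 at the preset correlation, and adjusted p = 0.137 with an estimated correlation. With an estimated correlation none of the 26 tested lists passed in any comparison. That form of the test rests on 3 residual degrees of freedom and has little power, so it neither bears out nor excludes a change.

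Epithelial junction genes went the other way, with 15 of 16 above 0 and a median of 0.81. CDH1 rose (2.25, adjusted p = 0.0051, limma), and 8 rose when adjusted over the list alone, whereas the tight junction gene CLDN1 (1.99) and the desmosomal cadherin DSG3 (1.34) did not pass over all genes. The list had an adjusted p of 3.18e-08 at the preset correlation, and adjusted p = 0.325 with an estimated correlation. Of 20 basal mammary genes 18 were above 0, with a median of 0.48. Of these KRT16 rose (1.5), 7 rose when adjusted over the list alone, and KRT17 (1.09) and KRT5 (0.80) did not pass over all genes (list adjusted p = 1.55e-05, and adjusted p = 0.157 with an estimated correlation). Reads shared between near-identical keratins or between the small proline-rich proteins could be split in counting, so KRT16, KRT17 and SPRR1B are uncertain to that extent. In the squamous differentiation list 6 of 11 were above 0, with a median of 0.17. SPRR1B, a cornified envelope protein, rose (1.42), 3 rose when adjusted over the list alone, and TGM1, the keratinocyte transglutaminase, had 1.25 with an adjusted p of 0.0662 (list adjusted p = 0.0223, and adjusted p = 0.383 with an estimated correlation). The call of the squamous list was lost without control A (adjusted p = 0.0505, median 0.09), control B (0.104, median 0.05) or replicate A of the group without EGF (0.185), with controls A and B averaged (0.0687, median 0.07) and at a mean of at least 50 (0.326). Its median was 0.45 without control P4, 0.28 without replicate B of the group without EGF and -0.06 among genes with a mean of at least 50. The junction median was 0.32 with no filter. Without replicate B of the group without EGF the basal median was 0.30 and CLDN1 was at 1.22.

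Markers of fibroblasts, a cell type that a mammary culture could hold, were also higher, with 9 of 10 above 0 and a median of 1.12. The microfibril gene MFAP5 (2.20), the fibrillar collagens COL3A1 (1.96) and COL1A1 (1.70), the protease FAP (1.40) and the matrix protein DPT (1.40) rose, and 8 rose and 1 fell when adjusted over the list alone. The list had an adjusted p of 3.44e-07, and adjusted p = 0.137 with an estimated correlation. The mesenchymal list had a median of 0.07, with 10 of 18 above 0 and 1 that rose when adjusted over the list alone (adjusted p = 0.82). Targets of TGF-beta had a median of 0.28 with 15 of 19 above 0. Of these COL1A1 and TGFBI (1.35) rose, 3 rose and 1 fell when adjusted over the list alone, and ID2 had 1.38 without passing (list adjusted p = 0.0074, and adjusted p = 0.251 with an estimated correlation).

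The list of other growth factors and receptors had 14 of 19 above 0 and a median of 0.15. Here IGFBP3 and the fibroblast growth factor receptor FGFR2 (1.47) rose, 4 rose when adjusted over the list alone, and FGFR3 (2.06) and IGFBP2 (2.01) had adjusted p of 0.101 and 0.126 (list adjusted p = 0.0031, and adjusted p = 0.240 with an estimated correlation). In the interferon-stimulated list 11 of 15 were above 0, with a median of 0.30. The RNA sensor IFIH1 (1.06) and IFIT2 (0.97) rose, and 4 rose when adjusted over the list alone (list adjusted p = 0.0027, and adjusted p = 0.251 with an estimated correlation). All 13 mitochondrially encoded genes were above 0, with a median of 0.26 and none past the test alone (list adjusted p = 0.0019, and adjusted p = 0.714 with an estimated correlation). Without control P4 the medians of these lists were 0.27 for growth factors and receptors, 0.17 for interferon-stimulated and 0.16 for mitochondrial genes. They were 0.23, 0.19 and 0.12 without replicate A of the group without EGF, where the mitochondrial call was lost (adjusted p = 0.0767). Without its replicate B the growth factor and mitochondrial medians were 0.28 and 0.43. The interferon median was 0.17 with no filter, and the interferon call was lost among genes with a mean of at least 50 (adjusted p = 0.0512).

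The other lower lists held no gene that passed singly. All 20 ribosomal protein genes were below 0, with a median of -0.50 (list adjusted p = 0.000128, and adjusted p = 0.756 with an estimated correlation). Ribosomal protein genes also differed between the passage 6 and passage 4 controls, with a median of -0.80, and at passage 6 alone the median of this comparison was -0.24. Hypoxia and glycolysis genes had a median of -0.34, with BNIP3 at -0.78 (list adjusted p = 0.0144, and adjusted p = 0.395 with an estimated correlation). Cholesterol synthesis genes had a median of -0.30 with 18 of 19 below 0 and HMGCS1 at -1.07 (list adjusted p = 0.0201, and adjusted p = 0.925 with an estimated correlation). The hypoxia call was lost without replicate B of the group without EGF (adjusted p = 0.059, median -0.20), and the cholesterol call without control A (0.117, median -0.18), without control B (0.174, median -0.16) and without that replicate B (0.660, median -0.03). Both were also lost at a mean of at least 50 (0.0512 and 0.0676), and the cholesterol call with controls A and B averaged (0.135, median -0.17). The cholesterol median was -0.69 without control P4 and -0.66 without replicate A of the group without EGF. HMGCS1 was at -1.75 without that replicate A and at -0.39 without replicate B.

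Several lists did not pass in this comparison. Matrix proteases and integrins had a median of -0.21 (adjusted p = 0.879), although MMP1 fell and the protease inhibitor TIMP3 (2.05) and the integrin subunits ITGB6 (1.97) and ITGB8 (1.48) rose, and 5 rose and 4 fell when adjusted over the list alone. Targets of FOXO had a median of 0.15 (adjusted p = 0.308), and SESN3 rose (1.2). EGFR ligands and receptors had a median of 0.25 (adjusted p = 0.64), with NRG1 at 1.11 (0.58 without replicate B of the group without EGF) and TGFA at -0.70, and 2 rose and 1 fell when adjusted over the list alone. DNA replication, mitosis and homologous recombination genes had medians of -0.16, -0.08 and 0.06 (adjusted p = 0.413, 0.586 and 0.730). Targets of p53 had -0.08 (adjusted p = 0.165, 1 lower when adjusted over the list alone), luminal mammary genes -0.13 (0.526, 1 higher and 2 lower over the list alone), YAP targets 0.12 (0.211), replication-dependent histones 0.25 (0.122) and amino acid and unfolded protein stress genes -0.12 (0.667). The NF-kB and secretory inflammatory list had a median of 0.15, a mean of -0.02 and a lower test direction (adjusted p = 0.879). Of cell type markers, endothelial genes had a median of 0.35 over 4 tested members (adjusted p = 0.586), and 0 haematopoietic genes passed the filter.

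In this comparison siRNA and medium differed together. Among passage 6 libraries alone 959 genes passed, 533 higher and 426 lower, with all 146 genes among them, and the lists of DNA replication (median -0.56, adjusted p = 4.75e-05), mitosis (-0.22, 0.0013), homologous recombination (-0.23, 0.0148), YAP targets (0.28, 0.0111) and FOXO targets (0.52, 0.0017) then passed with a passage term, and none of these with an estimated correlation (adjusted p from 0.590 to 0.686). Without replicate B of the group without EGF the medians were -0.29 for DNA replication, -0.10 for homologous recombination, which no longer passed (adjusted p = 0.0933), and 0.16 for YAP targets. Without replicate A they were -0.90 for DNA replication and -0.37 for homologous recombination. The interferon and mitochondrial medians with that term were 0.17 and 0.16. They were 0.07 and 0.07 without replicate A of the group without EGF, and 0.28 and 0.27 without its replicate B. With a passage term 950 genes passed over all 6 libraries (limma), 42 without control A and 45 without control B. Without replicate A or B of the group without EGF the count was 8964 or 6975, where controls A and B alone give the spread.

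**Figure D1:**
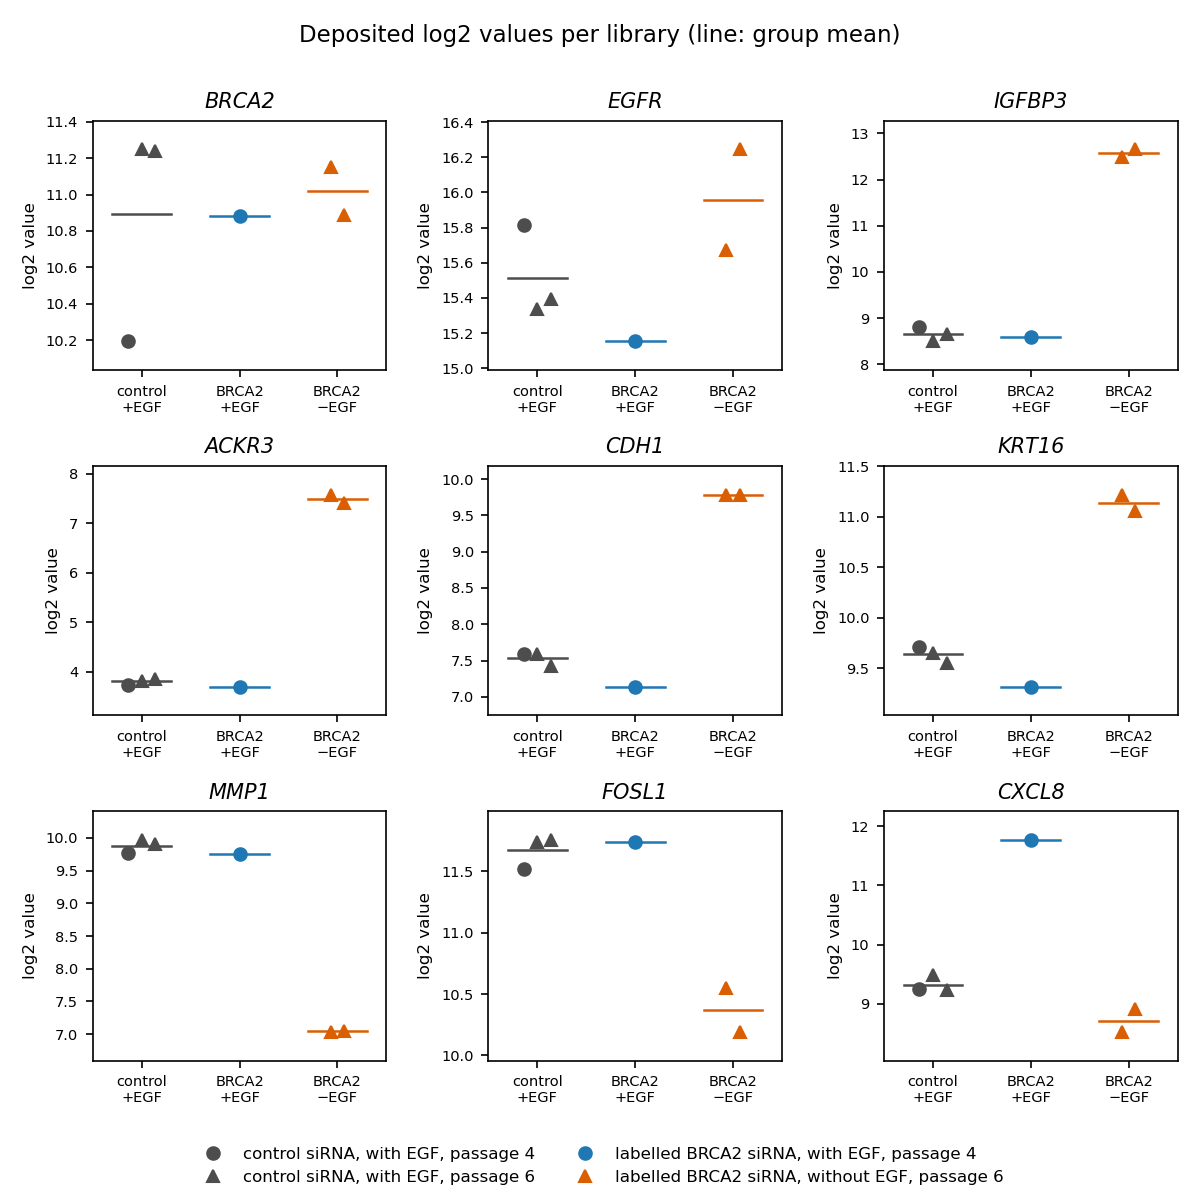
Deposited log2 values (y axis) of 9 genes in each library of the 3 groups (x axis), with circles for passage 4, triangles for passage 6 and a line at each group mean. IGFBP3 lies at 12.49 and 12.65 in the libraries without EGF and between 8.50 and 8.81 in the controls, while BRCA2 is lowest, at 10.19, in control P4.

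The second comparison asked what differed between the library labelled BRCA2 siRNA with EGF (n = 1) and control siRNA with EGF (n = 3), in the same medium. Its direction holds by label only, since BRCA2 does not bear out the labels at passage 4 and does not settle them either. Chemokine genes had the largest positive differences of all genes tested. CXCL8, the neutrophil chemoattractant interleukin 8, was at 11.77 against 9.32 ± 0.14 (SD), a log2 difference of 2.45. CXCL1 was at 13.69 against 10.99 ± 0.57 (SD), and CXCL3 was at 10.97 against 8.35 ± 0.17 (SD). The spread in the limma fit includes the difference of control P4 from controls A and B, so a lack of calls in it says little. With limma no gene passed the adjusted test (0 of 14763, 412 at an unadjusted p under 0.05 against 738 by chance), and the smallest adjusted p was 0.469, for CXCL8.

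All 17 tested genes of the NF-kB and secretory inflammatory list were above 0, with a median of 0.97. None passed over all genes, and 5 rose when adjusted over the list alone. The list had an adjusted p of 4.33e-16 by limma camera at the preset correlation, and adjusted p = 0.254 with an estimated correlation. Between the passage 4 libraries alone its median was 0.81, with log2 differences of 2.51 for CXCL8, 3.35 for CXCL1 and 2.70 for CXCL3. In the fit with a passage term, which tests that pair with the spread of the other libraries, the list had an adjusted p of 7.50e-05, and adjusted p = 0.616 with an estimated correlation, and none of the 3 genes passed (smallest adjusted p 0.0625, for CXCL1, limma). CXCL1 and CXCL3 are close paralogs, and how shared reads were counted is not given in the sources used here.

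Other genes with small p were the sulfatase SULF1 (1.02) and the calcium-binding S100A9 (1.60) on the higher side, and ITGA10 (-0.68), the prostaglandin receptor PTGER4 (-0.80), OLFML2A (-0.67), KIAA1671 (-0.65) and the desmosomal plakin PPL (-0.81) on the lower side, none of which passed. The squamous list had a median of 0.29, with S100A8 at 1.62 and 2 that rose when adjusted over the list alone (list adjusted p = 0.000225, and adjusted p = 0.254 with an estimated correlation). Fibroblast markers were all above 0, with a median of 0.24, led by the proteoglycans LUM (1.82) and DCN (1.71), and 2 rose when adjusted over the list alone (list adjusted p = 9.53e-07, and adjusted p = 0.254 with an estimated correlation). Interferon-stimulated genes (median 0.16) and replication-dependent histones (0.25) had list adjusted p of 0.0076 and 0.0073, and adjusted p = 0.381 and 0.503 with an estimated correlation.

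On the lower side, all 13 mitochondrially encoded genes were below 0, with a median of -0.37 (list adjusted p = 6.10e-08, and adjusted p = 0.503 with an estimated correlation). Epithelial junction genes had a median of -0.23, with CDH3 at -0.50 and DSG2 at -0.48, and stress genes of the unfolded protein response had -0.36, with the chaperone HSPA5 at -0.68. Other growth factors and receptors had -0.31, with the receptors MET at -0.61 and AXL at -0.60. These 3 lists each had an adjusted p of 0.000313, and adjusted p = 0.577, 0.503 and 0.254 with an estimated correlation. Targets of YAP had a median of -0.24 (list adjusted p = 0.0084, and adjusted p = 0.689 with an estimated correlation). The lists that did not pass had medians of 0.26 for DNA replication, 0.13 for ribosomal proteins, 0.10 for hypoxia and glycolysis (with EGLN3 at 1.03), 0.10 for ERK feedback targets, 0.05 for homologous recombination, 0.04 for cholesterol synthesis, 0.01 for mesenchymal genes (test direction higher, mean -0.00), -0.01 for EGFR ligands and receptors, -0.02 for mitosis, -0.08 for FOXO targets, -0.10 for p53 targets, -0.12 for basal mammary genes, -0.12 for TGF-beta targets, -0.13 for matrix proteases and integrins, -0.14 for luminal mammary genes (1 rose when adjusted over the list alone) and -0.09 for endothelial markers (test direction higher), with adjusted p from 0.0773 to 0.902.

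The lone library was assumed to vary like those of the other groups, and without control P4 the interferon, junction, YAP and histone lists no longer passed (adjusted p = 0.234, 0.0864, 0.269 and 0.184; medians 0.04, -0.14, -0.09 and 0.23). With no filter the interferon, squamous and junction medians were 0.06, 0.10 and -0.15. At a mean of at least 50 the squamous and fibroblast medians were 0.54 and 0.66. With a passage term 3436 genes had an unadjusted p under 0.05 and 0 passed adjustment (limma). Controls A and B alone give the spread of that fit when replicate A or B of the group without EGF is left out. With all 6 libraries the spread comes from both pairs. The mitochondrial, squamous and growth factor receptor lists no longer passed (adjusted p = 0.151, 0.355 and 0.0988; medians -0.19, 0.06 and -0.28). The junction, YAP and fibroblast medians were then -0.38, -0.50 and 0.38. With that term, where control P4 is the only control set against the library, 6 further lists passed: DNA replication (median 1.01, adjusted p = 2.11e-09), homologous recombination (0.56, 2.33e-07), ribosomal proteins (-0.39, against 0.13 over all 6 libraries, 4.84e-07), cholesterol synthesis (0.56, 5.67e-06), mitosis (0.29, 8.97e-05) and FOXO targets (-0.43, 0.0045), each with adjusted p = 0.616 with an estimated correlation.

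The third comparison set the libraries labelled BRCA2 siRNA without EGF (n = 2, passage 6) against the library with that label and EGF (n = 1, passage 4), so that medium and passage differed together. The label of the latter is not borne out by BRCA2, which moved at passage 4 with other homologous recombination genes. IGFBP3 was 15.8-fold higher without EGF, a log2 difference of 3.98 ± 0.19 (standard error, adjusted p = 0.0085, limma), and ACKR3 was 13.9-fold higher, at 3.80 ± 0.19 (adjusted p = 0.0085, limma). CDH1 rose by 2.64 (adjusted p = 0.0173) and KRT16 by 1.82 (adjusted p = 0.0319). CXCL8 and MMP1 fell by 3.06 and by 2.72 (adjusted p = 0.0233 and 0.0155). In all, 30 of 14763 genes passed, 26 higher and 4 lower, and 2423 had an unadjusted p under 0.05. The count was 11 with controls A and B averaged into 1 library, 2404 without control P4, 9 without control A, 10 without control B, and 0 without replicate A or without replicate B of the group without EGF (1857 and 1239 genes at an unadjusted p under 0.05). Every gene call named for this comparison was thus lost without either of those libraries, where both groups have 1 library. The differences ran from 3.90 to 4.21 for IGFBP3, from 2.60 to 2.72 for CDH1 and from -3.25 to -2.87 for CXCL8 over 16 alternatives. Some of these, such as a filter or leaving out a control library, cannot change a difference between the other groups.

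Next in size among the increases were KLK5 (3.71, adjusted p = 0.0499), SERPINB13 (3.26, 0.0135) and EPHB6 (3.12, 0.0306). The other lower genes past the threshold, named after their values were seen because they fall outside the naming rule, were the noncoding RNA LINC02582 (-2.25) and ENSG00000269927 (-1.95), which has no symbol in the name table. SH2D2A (-2.15), BNIP3P1 (-1.49) and the matrix protein SMOC1 (-1.71) had adjusted p of 0.0503, 0.0565 and 0.0585. BNIP3P1 is a pseudogene of BNIP3, which had -1.28 without passing, so the values of that pair are uncertain.

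Epithelial junction genes had a median of 0.94 with 15 of 16 above 0, where CDH1 rose, 9 rose when adjusted over the list alone, and CLDN1 had 2.05 without passing (list adjusted p = 1.63e-08, and adjusted p = 0.383 with an estimated correlation). Feedback targets of ERK had a median of -1.05 with 18 of 20 below 0, where none fell over all genes, 11 fell and 1 rose when adjusted over the list alone, and FOS (-1.82) and the ERK phosphatase DUSP6 (-1.56) had the largest differences (list adjusted p = 2.65e-07, and adjusted p = 0.194 with an estimated correlation). In the NF-kB list 16 of 17 were below 0, with a median of -0.81. CXCL8 fell, 6 fell when adjusted over the list alone, and CXCL1 had -3.16 with an adjusted p of 0.0664 (list adjusted p = 2.74e-05, and adjusted p = 0.411 with an estimated correlation). The lone library with EGF was high in the NF-kB list, with a mean over members of the value minus the gene mean of 0.98. That mean was -0.56 (A) and 0.15 (B) without EGF, and -0.04 (P4), -0.19 (A) and -0.35 (B) in the controls with EGF. Against those controls the libraries without EGF had an NF-kB median of 0.15, with CXCL8 at -0.61, not past the test. Other growth factors and receptors had 17 of 19 above 0 and a median of 0.64, with IGFBP3 past the test, 9 that rose when adjusted over the list alone and IGFBP2 at 2.60 (list adjusted p = 2.09e-05, and adjusted p = 0.194 with an estimated correlation). The NF-kB median was -0.43 without replicate A of the group without EGF, CLDN1 was at 1.27 without its replicate B, and the junction median was 0.50 with no filter.

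All 13 mitochondrially encoded genes were above 0, with a median of 0.62 (list adjusted p = 9.18e-07, and adjusted p = 0.471 with an estimated correlation). Basal mammary genes had a median of 0.52, where KRT16 rose and 6 rose when adjusted over the list alone (list adjusted p = 8.59e-05, and adjusted p = 0.210 with an estimated correlation). Targets of TGF-beta (0.40) and of YAP (0.47) and fibroblast markers (0.80, with MFAP5 at 2.13 and COL1A1 at 1.30) had list adjusted p of 0.0058, 0.0231 and 0.0388, and adjusted p = 0.355, 0.892 and 0.383 with an estimated correlation. When adjusted over the list alone, 5 rose and 2 fell among TGF-beta targets, 5 rose and 3 fell among fibroblast markers, and 1 fell among hypoxia and glycolysis genes. The YAP call was lost without replicate B of the group without EGF (adjusted p = 0.202, median 0.27) and with no filter (0.0772). The fibroblast call was lost in 7 alternatives, at a mean of at least 50 (median 0.04, adjusted p = 0.770), with a passage term (0.29, 0.294), with no filter (0.43, 0.232), without control P4 (0.157), with TMM or median-of-ratios rescaling (0.0575 and 0.0545) and without replicate A of the group without EGF (0.0531). All 20 ribosomal protein genes were below 0, with a median of -0.64 (list adjusted p = 7.93e-05, and adjusted p = 0.878 with an estimated correlation). Hypoxia and glycolysis genes had -0.59, with ANGPTL4 at -1.87, and cholesterol synthesis genes had -0.39 (list adjusted p = 0.0047 and 0.0267, and adjusted p = 0.383 and 0.940 with an estimated correlation). The cholesterol call was lost without replicate B of the group without EGF (adjusted p = 0.473, median -0.19) and at a mean of at least 50 (0.0562), and its median was -0.74 without replicate A. The lists that did not pass had adjusted p from 0.0789 to 0.996. Their medians were -0.41 for DNA replication, 0.41 for amino acid and unfolded protein stress, 0.31 for endothelial markers, -0.11 for histones, -0.07 for luminal genes, 0.06 for FOXO targets (with SESN3 at 1.18, adjusted p = 0.07), 0.02 for matrix proteases and integrins (where MMP1 fell, with TIMP3 at 2.45, adjusted p = 0.0565) and -0.01 for homologous recombination. In 6 more lists the median, the mean and the test differed in sign. EGFR ligands and receptors (median -0.21, mean 0.07) and interferon-stimulated genes (-0.06 and 0.15) had a higher test direction, as had squamous genes (0.06 and -0.13). Targets of p53 (0.05 and -0.04), mitosis genes (-0.05 and 0.0069) and mesenchymal genes (-0.01 and 0.04) had a lower one. When adjusted over the list alone, the lists that did not pass had 5 higher and 3 lower matrix genes, 2 and 2 squamous genes, 2 and 0 interferon-stimulated genes, 1 and 1 EGFR ligands or receptors and 1 and 0 FOXO targets.

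With a passage term, which takes the passage difference of the controls off, 569 genes passed (326 higher, 243 lower, limma), and BRCA1 had -1.25 with an adjusted p of 0.0473, against a range of 0.0473 to 0.996 over the 16 alternatives run for it. The count was 0 without control A (2078 genes at an unadjusted p under 0.05), 2 without control B, and 9066 or 7493 without replicate A or B of the group without EGF, where controls A and B alone give the spread. Without the passage term BRCA1 differed by only 0.0079. Its -1.25 comes from the passage difference of the controls, 1.26, which that term takes off. The NF-kB median with that term was -0.71, but -0.32 without replicate A of the group without EGF and -1.11 without its replicate B. With the passage term and all libraries the ERK, mitochondrial and cholesterol medians were -0.68, 0.36 and -1.39, ANGPTL4 was at -3.30 and IGFBP2 at 1.28. The mitochondrial list then no longer passed without control A (adjusted p = 0.0519), control B (0.0677) or replicate A of the group without EGF (0.210, median 0.20). The ribosomal median turned to 0.17 (adjusted p = 0.081) and the fibroblast and hypoxia lists no longer passed (0.294 and 0.0571), while DNA replication (median -1.68, 2.64e-09), homologous recombination (-0.89, 1.08e-06), mitosis (-0.57, 5.47e-06) and FOXO targets (0.76, 0.000226) did, each with adjusted p = 0.588 with an estimated correlation. These last calls rest on control P4, the only library labelled control at passage 4, which had a DNA replication score of -0.81 against 0.27 in the library labelled BRCA2 siRNA with EGF and 0.16 and -0.51 without EGF. Without the passage term the 4 medians were -0.41, -0.01, -0.05 and 0.06, and none passed.

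**Figure D2:**
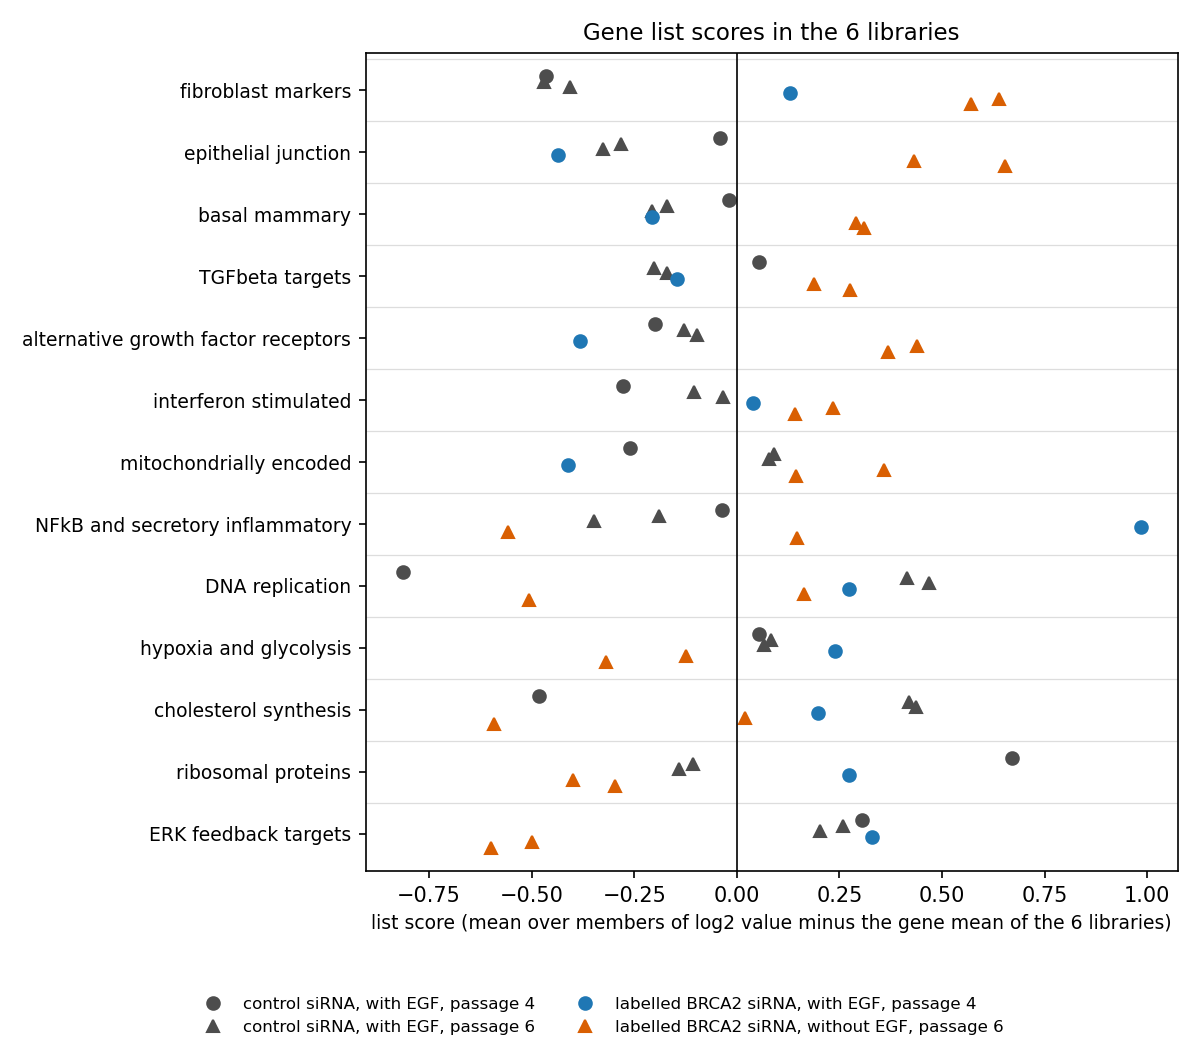
Scores of 13 gene lists (y axis) in the 6 libraries, each the mean over members of the log2 value minus that gene's mean over the 6 libraries (x axis), with circles for passage 4 and triangles for passage 6. ERK feedback targets score -0.50 and -0.60 without EGF and between 0.20 and 0.33 in the libraries with EGF, and the NF-kB list scores 0.98 in the lone library labelled BRCA2 siRNA with EGF.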

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

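Averaging controls A and B and the crossed replicate block were chosen after seeing the data, as were all alternatives for the passage difference of the controls and the passage term with 1 library left out. Counts are of genes passing limma. For BRCA2 siRNA without EGF against control siRNA with EGF, 146 became 87 with no filter, 94 at a mean of at least 50, 6 with the replicate block, 950 with a passage term, 959 among passage 6 libraries and 37 with controls A and B averaged. For BRCA2 siRNA without EGF against BRCA2 siRNA with EGF, 30 became 18 with no filter, 13 at a mean of at least 50, 56 without trend and robust prior, 0 with the replicate block (1008 at an unadjusted p under 0.05), 569 with a passage term and 11 with controls A and B averaged. For BRCA2 siRNA with EGF against control siRNA with EGF, limma gave 0 in every alternative run other than a passage term with replicate A or B of the group without EGF left out, which gave 7646 and 7651 (412 at an unadjusted p under 0.05 with all 6 libraries). Leaving out 1 library gave 0 to 951 for the group without EGF against control siRNA and 0 to 2404 for it against BRCA2 siRNA with EGF. With fewer samples the spread is estimated from fewer residual degrees of freedom, and a filter changes the number of genes tested; for the other changes the cause was not tested.

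The number of lists called (12, 10 and 12) was 0 in each comparison with an estimated correlation and otherwise within 1.5 times. Of list medians, 524 results under alternatives kept their call, 33 lost it and 1 turned its test direction, the ribosomal list of BRCA2 siRNA without against with EGF (0.17 with a passage term). Among those that lost the call, the squamous median without EGF against control siRNA also changed sign (-0.06 at a mean of at least 50). Whether the letters A and B pair the samples is not settled. Their differences at passage 6 correlated at -0.172 across genes, which are not independent replicates. Controls A and B differed by an SD of only 0.119 over tested genes, so a shared effect could hardly show in that correlation. Crossing the letters in the replicate block gave 112 genes against control siRNA and 10 against BRCA2 siRNA with EGF.

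Of named genes, 1525 results under alternatives kept direction and side of the threshold, 291 lost the threshold, 59 gained it and 19 reversed. All 19 were of BRCA2 or BRCA1, neither of which passed in the main fit of all 6 libraries without a passage term. Of these, BRCA1 without against with EGF passed in the fit with a passage term. Values of the passage 4 pair moved by more than the SD of the controls for 13 named genes. The fit with a passage term tests the same pair, and over all 6 libraries no gene passed in it (3436 at an unadjusted p under 0.05, limma). Without EGF against control siRNA, BRCA2 was -0.23 with a passage term and at passage 6 alone and -0.23 to 0.30 with 1 library left out, and BRCA1 -0.21 with a passage term and at passage 6 alone and -0.21 to 0.42 with 1 left out. With EGF against control siRNA, BRCA2 was 0.047 with the replicate block, 0.69 with a passage term, 0.16 with controls A and B averaged and -0.36 to 0.16 with 1 left out, and BRCA1 1.04 with a passage term and between the passage 4 libraries and -0.22 to 0.41 with 1 left out. Without against with EGF under BRCA2 siRNA, BRCA2 was -0.91 with a passage term and -0.065 with the crossed block, and BRCA1 was -1.25 with a passage term, -0.11 with the replicate block, -0.23 with the crossed block and -0.13 to 0.14 with 1 left out. Of the 55 named calls, 49 were lost with the replicate block, 33 without control A, 30 without control B, 30 with controls A and B averaged and 21 with no filter. Without replicate A or replicate B of the group without EGF, all 55 named gene calls lost the threshold, which says little of their stability, since a group is then left with 1 library and fewer degrees of freedom. Count tests with edgeR or DESeq2 were not run, since whole reads could not be recovered from the log2 values, and comparisons with the lone library have no value without it. Depth is unknown, so what it limits could not be assessed.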

Other observations

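The tests of passage acting alike in both siRNA groups, of an exchange of labels at passage 4, of fibroblast-like cells, of passage as the source of the fibroblast markers and of the spread between single cultures were chosen after the results were seen, as were the genes named in this part and every alternative for the passage difference. The other tests were written down before their values were seen.

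The following 7 genes are in none of the fixed lists and passed in the libraries labelled BRCA2 siRNA without EGF against control siRNA with EGF. They were chosen after their values were seen, so they show no enrichment of any kind of gene. The desmosomal cadherins DSG1 and DSC1 were higher by 2.75 ± 0.16 and 1.80 ± 0.14 on the log2 scale (standard error, adjusted p = 0.0051 and 0.0096, limma), and the desmosomal membrane protein PERP by 0.88 ± 0.12 (adjusted p = 0.044). The fibrillar collagen COL5A2 was higher by 1.57 ± 0.16 and the basement membrane protein NID1 by 1.30 ± 0.16 (adjusted p = 0.0209 and 0.036). CYP1A1 and CYP1B1, targets of the aryl hydrocarbon receptor, were higher by 2.00 ± 0.25 and 1.37 ± 0.19 (adjusted p = 0.0333 and 0.0468). Each of them was higher in both libraries without EGF than in all 3 controls, and each lost the threshold without replicate A of the group without EGF (adjusted p from 0.124 for DSG1 to 0.282 for PERP) and without replicate B (0.0999 for DSG1 to 0.437 for CYP1B1).

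Between the libraries labelled control, passage 6 (n = 2) and passage 4 (n = 1) differed in groups of genes, and BRCA2 does not settle the label of the latter. DNA replication genes had a median log2 difference of 1.28 (passage 6 minus passage 4), and 13 of 21 rose, among them MCM6 (1.83) and RRM2 (1.52). Of the mitosis and homologous recombination lists 10 and 12 of 20 rose, with medians of 0.53 and 0.89, and the cholesterol synthesis median was 0.89, where 7 of 19 rose. All 20 ribosomal protein genes fell, with a median of -0.80. Of FOXO targets 7 of 17 fell, with a median of -0.69, led by FBXO32, a ubiquitin ligase subunit (-3.72), and the autophagy gene GABARAPL1 (-1.98). The ferritin genes FTH1 (-1.97) and FTL (-1.95) fell as well, and BRCA2 (1.05) and BRCA1 (1.26) rose. Targets of YAP had a median of -0.44 (4 fell) and mitochondrially encoded genes 0.39 (2 rose). These 8 lists had adjusted p of at most 0.0058 by limma camera at the preset correlation and adjusted p = 0.760 with an estimated correlation. Each passed at the preset correlation in all 13 alternatives run. None of these alternatives leaves out control P4, on which the whole difference rests, and that form of the test compares genes. Passing in them therefore says little of how far single cultures differ. In all 2963 genes passed (1138 higher, 1825 lower, limma), a count that rests on the closeness of control A and control B. It was 0 without control A (2959 genes at an unadjusted p under 0.05), 0 without control B (2674), 0 with both averaged (2770) and 0 with no filter (7341), and all genes named here lost the threshold in these 4 alternatives. It was 9835 and 9849 without replicate A or B of the group without EGF.

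For the lower DNA replication genes of control P4, the median was 1.32 after TMM rescaling. That rescaling shifted the libraries by only -0.03 to 0.04 on the log2 scale. By that measure the libraries already had a near-common scale. The rescaling could hardly move the median, so it is no separate test of scaling. The tables count against a bias of transcript length and GC content. After a smooth trend over both was taken off, the median was 1.31 (all 21 members had a length). Passage itself acting alike in both siRNA groups cannot be told apart from the state of that one culture. The library labelled BRCA2 siRNA at passage 4 lay only -0.19 from the passage 6 controls in the list median, between the bounds set for the test, and siRNA differs between the passage 4 libraries. An exchange of the labels of these 2 libraries stays open too, since BRCA2 differed between them by 0.12 more than the median of 20 homologous recombination genes (SD 0.32), too little to tell a targeted gene from one that moved with that list. After the recovery period its level gives no measure of the earlier knockdown, so it could not decide an exchange. If the labels were exchanged, the passage difference would be one between siRNAs as well.

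The higher fibroblast markers without EGF are not accounted for by passage, since the median at passage 6 alone was 1.16. Fibroblast-like cells in the cultures without EGF may contribute, and the values do not decide this. Of 10 markers 8 had a 95% interval above 0 against the controls, and 1, COL6A3 (-0.75, interval -1.13 to -0.37), had an interval that ends below 0.56, while an earlier form of this test, against the lone library labelled BRCA2 siRNA with EGF, had put DCN (-1.04), LUM (-0.98) and COL6A3 (-0.95) below 0 and was set aside because a single library excludes nothing. The most abundant markers in these libraries were COL3A1 (11.34 and 11.56), COL1A1 (10.76 and 10.55) and FAP (10.75 and 10.65). Of 12 markers fixed in the list, 10 passed the filter on low values in this epithelial line. COL1A2 and PDGFRA were not among the tested genes. Of the tested markers 2 are also in other lists (COL1A1 with TGF-beta targets, PDGFRB with growth factor receptors). A response of the epithelial cells to the medium or the siRNA is also open, as untested, because control siRNA without EGF was not analysed here.

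The NF-kB and secretory inflammatory genes of the lone library labelled BRCA2 siRNA with EGF had a median of 0.97 after TMM rescaling too. The shifts of that rescaling were small (-0.03 to 0.04 on the log2 scale), so it is no separate test of scaling. The spread between single cultures cannot be told apart from an effect of the siRNA. The list median differed by up to 0.79 between 2 libraries of one group (replicates A and B without EGF), against 0.97 in the comparison, and the group with EGF has 1 library here. An exchange of the labels at passage 4 is open as well, on the same difference of 0.12 for BRCA2, and would place these higher genes in a library of control siRNA.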
